A study of Mus musculus with 18 samples.

How the data were processed

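RNA was measured in 18 left-ventricle samples of C57BL/6 mice, 3 in each of 6 groups: young WT, aged WT and Sesn2-KO, each after sham surgery or IR. Per the labels' protocols, RNA was purified with RNeasy columns, libraries were made with a stranded mRNA kit (TruSeq), and paired-end reads were taken on a NextSeq 500. The authors deposited 1 table per sample with a gene symbol and a whole-number count of fragments per gene, not normalized. Per the submitters' processing notes, FastQC, Bowtie2, TopHat2, HTSeq and SAMtools were used with the mouse build mm10; their versions, settings, strand option and gene annotation are not given in the sources used here. Each table held 24421 gene symbols and 2 summary lines, for fragments in no gene and fragments in more than 1 gene. The summary lines held 6.12% to 9.06% and 0.63% to 0.76% of the counts and stayed out of library sizes and tests. Gene positions and the longest transcript of each gene were taken from GENCODE M21 on GRCm38 by symbol, and 23334 symbols (95.5%) were found once.

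Groups were taken from the sample titles. Each sample is described as a heart of its own group, but nothing in the labels ties samples to litters, surgery days or sequencing batches, so p-values measure the spread between these samples. Replicates were compared by a chi-square test of their counts, and no pair was identical: chi-square per degree of freedom was 8.9 to 50.85. Counting intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules; a floor is 3 counts over the group.

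Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (13859 of 24421), library sizes were scaled by TMM, and 1 model with a mean for each of the 6 groups was fitted to all 18 libraries by quasi-likelihood with robust dispersion. The 9 comparisons were contrasts of that model: IR against sham in each of young WT, aged WT and Sesn2-KO, aged against young WT and Sesn2-KO against young WT within sham and within IR, and the difference of IR responses of aged WT and of Sesn2-KO from young WT. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. CPM values use the TMM-scaled library sizes, except those of receptor genes, which use raw library totals. A log2 fold change is edgeR's estimate, with a standard error from its test statistic. Chance values of similarity and overlap between comparisons that share young libraries came from 20 simulations of unchanged groups, those of overlap added after seeing the data.

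A collection of 44 gene lists (pathways, stress programmes and markers of the cell types a left ventricle can hold) was tested, where at least 5 members were tested as genes, with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01). Camera was run again with a correlation estimated for each list, and fry was run as a self-contained test. Adjusted p-values of lists are over the 41 lists tested in a comparison. For each list the number of members called was counted over all genes and adjusted over the list alone.

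Genes named in the text followed a rule. For each comparison these were up to 8 genes with the highest and 8 with the lowest log2 fold change among called genes with a mean of at least 1 CPM and no overlap of CPM between the groups (no overlap condition for a difference of responses), leaving out predicted and clone-named genes. From each described list, up to 4 members with the smallest p were named, and Sesn2, Sesn1, Sesn3 and the genes of the sex-linked and substrain lists were always included. The groups, tests, lists, this rule and the alternatives were fixed before the data were examined, apart from those stated to be added.

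The same steps were tested on simulated data drawn from the real means and library sizes, with known changes in a seeded set of genes. For IR against sham in young WT (13750 genes), 67% of 2-fold and 93% of 4-fold changes were recovered, with 8 false calls. For IR against sham in Sesn2-KO (13730 genes) the shares were 74% and 91%, for aged against young sham hearts (13734 genes) 71% and 92%, for the difference in IR response between aged and young WT (13751 genes) 35.4% and 78%, and for that between Sesn2-KO and young WT (13744 genes) 32.3% and 73.7%. A list moved in the simulation was called and the other 40 lists were not. Simulated genes were drawn independently, so this does not bear on false calls of lists whose members vary together.

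Alternatives were DESeq2 size factors, upper quartile scaling, no filter on low counts, the DESeq2 1.42.0 Wald test, limma voom with quality weights, a fit of the compared groups alone, the replicate number as an added term, and leaving out each library in turn. Added after seeing the data were each library's slope of log2 CPM on transcript length as covariate, and leaving out 6 length-tilted libraries named below. Genes with close paralogues, such as Pydc3 and the Gbp and Tgtp families, may share fragments, so their counts are uncertain. Reads, splicing and the inserted or deleted sequence of the Sesn2 allele were not analysed here.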

Results

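Gene counts were analysed from 18 left-ventricle libraries of C57BL/6 mice, 3 in each of 6 groups, to ask how age and loss of Sesn2 alter the response of the heart to ischaemia and reperfusion (IR). Sesn2 encodes sestrin 2, a stress-induced regulator of AMPK and mTORC1 signalling. Young wild-type (WT) and Sesn2-knockout (Sesn2-KO) mice were 3 to 4 months old, aged WT mice 24 to 26 months. In the IR groups the left anterior descending coronary artery was closed for 45 min and the heart was reperfused for 24 h. Sham mice had the chest opened with the artery left open. Young WT mice came from Jackson, aged WT from Charles River and Sesn2-KO from the authors' own colony. Source thus changed with age and genotype. The libraries held 9404531 to 14458047 gene counts, and 13859 genes were tested. Adjusted p-values are edgeR's (quasi-likelihood, Benjamini-Hochberg) unless another tool is named. A value after ± is a standard error unless marked SD. A library is named by its group and replicate number, as in young sham 1. In 1 library of each group (young sham 1, young IR 3, aged sham 1, aged IR 3, Sesn2-KO sham 3 and Sesn2-KO IR 3) the deviation of gene counts from the group mean followed transcript length, with rank correlations of 0.31 to 0.48.

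Sesn2 counts followed the genotype labels in all 18 libraries. Sesn2 (chromosome 4, 132492032 to 132510501, GRCm38) had a counts-per-million (CPM) value of 3.78 ± 0.973 (SD, n = 12) in WT hearts, with a range of 2.56 to 5.96. In Sesn2-KO hearts it was at 0.202 ± 0.151 CPM (SD, n = 6), with 0 to 5 counts per library. The log2 fold change in Sesn2-KO against young WT was -4.42 ± 0.56 in sham hearts (adjusted p = 0.000371) and -3.99 ± 0.56 in IR hearts (adjusted p = 0.00461). Sesn2 was not called between IR and sham in young WT (log2 fold change -0.09, adjusted p = 0.93) or aged WT (-0.10, adjusted p = 0.911), nor between aged and young sham hearts (0.01, adjusted p = 1). Its paralogues Sesn1 and Sesn3 were not called in any of the 9 comparisons; Sesn1 was at -0.71 ± 0.19 in Sesn2-KO against young WT after IR (adjusted p = 0.121).

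Genes known to vary between C57BL/6 substrains differed in the Sesn2-KO hearts. Wdfy1 (chromosome 1, 79702262 to 79776143) rose in Sesn2-KO by 2.26 ± 0.23 on the log2 scale in sham hearts (adjusted p = 3.91e-05) and by 2.61 ± 0.23 in IR hearts (adjusted p = 4.98e-05). Ide, which encodes the insulin-degrading enzyme (chromosome 19, 37268743 to 37337852), had log2 fold changes of -1.21 ± 0.18 (adjusted p = 0.00122) and -1.35 ± 0.18 (adjusted p = 0.00291). Nnt, the mitochondrial transhydrogenase gene that carries a deletion in C57BL/6J, rose by 0.72 ± 0.14 in sham hearts (adjusted p = 0.00919) and was at 0.59 ± 0.14 in IR hearts (adjusted p = 0.0966), where it was called without young IR 1 (0.76, adjusted p = 0.0375). Entpd4 was not called. Of the Y-linked genes, Eif2s3y fell in Sesn2-KO sham hearts (-0.64 ± 0.12, adjusted p = 0.00602; not called without the length-tilted libraries) and was at -0.52 in IR hearts (adjusted p = 0.0734), while Ddx3y, Uty and Kdm5d were not called. None of these genes was called between aged and young WT. Within 10 Mb of Sesn2, 10 of 257 tested genes were called in Sesn2-KO sham hearts, against 672 of 13087 elsewhere (odds ratio 0.75, 95% interval 0.35 to 1.41, two-sided Fisher's exact p = 0.473). After IR the called genes were 2 of 257, Hmgn2 and Gpn2, against 55 of 13087 (odds ratio 1.86, interval 0.22 to 7.11, exact p = 0.301). Gpn2 (0.70 ± 0.14 after IR, adjusted p = 0.0448) falls outside the rule for named genes and was chosen after its values were seen. It was not called after IR without young IR 1, 2 or 3 or Sesn2-KO IR 2, nor in sham hearts without any library but young sham 3 (adjusted p 0.0667 to 0.24).

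**Figure D1:**
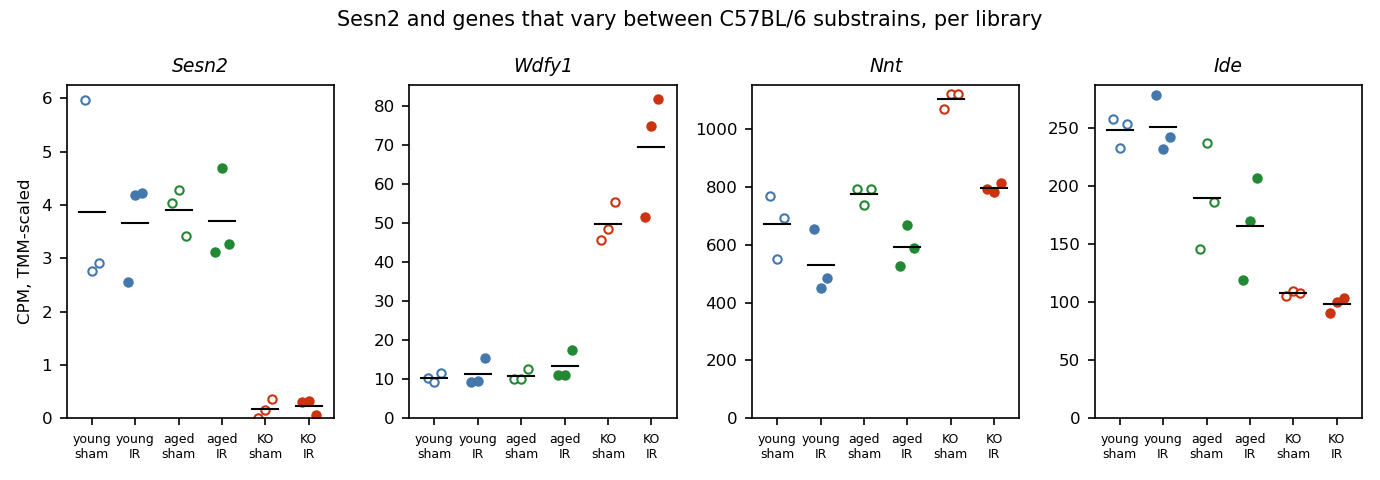
CPM (TMM-scaled, linear axes from 0) of Sesn2, Wdfy1, Nnt and Ide in each library, by group (open points sham, filled points IR, bars means of 3). The 6 Sesn2-KO libraries lie at or below 0.371 CPM for Sesn2.

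IR raised many inflammatory and matrix genes in young WT hearts. Spp1, which encodes osteopontin, went from 0.831 ± 0.231 CPM in sham to 114 ± 77.8 CPM in IR hearts (SD, n = 3 each), and Timp1 from 2.99 ± 0.843 to 127 ± 59.4 CPM. Lcn2, a neutrophil and acute-phase protein, went from 3.65 ± 1.24 to 239 ± 179 CPM, and the matrix metalloproteinase gene Mmp3 from 4.93 ± 0.869 to 67.3 ± 12.6 CPM. The log2 fold changes were 7.10 ± 0.68 for Spp1 and 5.41 ± 0.53 for Timp1 (both adjusted p = 3.56e-05), 6.04 ± 0.73 for Lcn2 (adjusted p = 0.000314) and 3.77 ± 0.29 for Mmp3 (adjusted p = 6.44e-06). Arg1 (7.38 ± 1.01), Sprr1a (6.35 ± 0.96), Tnc (6.05 ± 1.01) and Chil3 (5.73 ± 0.87) also rose, with adjusted p-values of 0.0007 to 0.00276. F10, the coagulation factor X gene, had 0 counts in the sham group and 99 after IR, at least 36.6-fold higher against a floor of 3 counts over the group. Steap1 had 1 and 86 counts, a ratio of 95.4 with a counting interval of 16.7 to 3810. Over all genes 841 were called, 578 higher and 263 lower. The count was 340 without young sham 1, 348 without young sham 3, and 1464, 432 and 272 without young IR 1, 2 and 3. It was 1318 by DESeq2's Wald test, 2637 by limma voom with quality weights, and 163 with the 6 young libraries alone in the fit. It was 2019 with the length trend as a covariate and 16 without the 6 length-tilted libraries, which left 2 mice per group. Of the 40 called genes named for this comparison, Mmp3, Clec4d, Ptx3, Ccl2 and Ccl7 stayed called without the length-tilted libraries, and 20 with the young libraries alone.

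Neutrophil and cytokine genes rose together in young WT hearts. Of 16 neutrophil markers 13 rose and 3 did not pass (15 rose adjusted over the list alone), with Clec4d at 4.09 ± 0.37 and a median of 4.21. Camera's adjusted p for the list was 1.8e-21, or adjusted p = 0.049 with an estimated correlation. Of 32 acute cytokine and chemokine genes 18 rose and 14 did not pass (24 rose adjusted over the list alone), among them Ptx3 (4.37 ± 0.42), Ccl2 (3.46 ± 0.34) and Ccl7 (3.23 ± 0.34). This list's camera adjusted p was 9.4e-23, and adjusted p = 0.049 with an estimated correlation. Of 34 fibrillar matrix genes 22 rose and 1 fell (27 and 1 adjusted over the list alone), with Lox at 2.92 and Loxl1 at 1.24. Camera gave 4e-16 for the matrix list, and adjusted p = 0.18 with an estimated correlation. Monocyte and macrophage markers rose in 12 of 28 (16 adjusted over the list alone), such as Msr1 (2.19) and Lgals3 (3.13), with a camera adjusted p of 4.9e-10 and adjusted p = 0.31 with an estimated correlation. Young IR 1 stood apart from young IR 2 and 3, at -11.3 against 19.9 and 28.6 on the first principal component, with a mean log2 CPM of 5.60 against 6.76 and 6.71 for matrix genes. Matrix genes that rose numbered 13 without young sham 1, young IR 2 or young IR 3 and 14 without young sham 3. Monocyte markers numbered 7 without young sham 1 or young IR 3.

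Some stress-response genes also rose in young WT hearts. Of 32 genes of the integrated stress response and ER stress, 12 rose and 20 did not pass (19 rose and 2 fell adjusted over the list alone), including Psat1 (1.75) and Slc3a2 (0.66). Camera's adjusted p was 1.3e-07, and adjusted p = 0.23 with an estimated correlation. Immediate early genes rose in 8 of 28 (10 adjusted over the list alone), with Junb at 1.35 and Ier3 at 0.95, and the list had a camera adjusted p of 3.4e-07 and adjusted p = 0.23 with an estimated correlation. Hmox1, the haem oxygenase gene, rose by 2.17 ± 0.22 on the log2 scale (adjusted p = 3.98e-05). Of 31 genes of cardiomyocyte contraction and ion handling, Mybpc3 fell (-0.59 ± 0.13, adjusted p = 0.0134) from 4040 ± 272 to 2680 ± 490 CPM (SD, n = 3 each); the other 30 did not pass, and 1 fell adjusted over the list alone. The list's median was -0.23 (camera adjusted p = 0.00079, adjusted p = 0.23 with an estimated correlation). Kdr fell (-0.75 ± 0.12, adjusted p = 0.00247), as did Fmod (-2.37 ± 0.49, adjusted p = 0.0107) and Xpnpep2 (-2.82, adjusted p = 0.0067). The 12 risen stress genes numbered 4, 6 and 7 without young sham 1, 2 and 3, and 18, 5 and 2 without young IR 1, 2 and 3. The 8 immediate early genes numbered 4 without young sham 3 or young IR 3. Mybpc3 was not called without young sham 1 or 3 (adjusted p 0.0505 and 0.0576). Without young IR 1, 4 contraction genes fell. Fmod was not called without young IR 2 or 3 (0.0508 and 0.064).

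Some interferon-response and antigen-presentation genes were lower after IR in young WT, with smaller changes without young sham 3. Of 40 interferon genes, 9 fell and 31 did not pass (20 fell adjusted over the list alone), with a median of -1.02, a camera adjusted p of 4.3e-07 and adjusted p = 0.61 with an estimated correlation. Examples were the chemokine gene Cxcl9 (-2.78 ± 0.54, adjusted p = 0.00722), Gbp5 (-2.06) and Gbp3 (-2.43), and, outside the list, Gbp4 (-2.67), Cd274 (-3.36), Tgtp1 (-2.77) and Tgtp2 (-2.95). In young sham 3 the interferon-inducible GTPase gene Igtp was at 1640 CPM, against 29 and 46.2 CPM in the other young sham libraries and 27.8 to 47.4 CPM after IR. Without that library 1 interferon gene fell, the list's median was -0.13 and its camera adjusted p was 0.1. The 9 genes became 19 and 17 without young sham 1 and 2, and 4, 1 and 1 without young IR 1, 2 and 3. Of 11 genes of MHC class II presentation, 4 fell (5 adjusted over the list alone): H2-Aa (-1.70), H2-Eb1 (-1.64), Ciita (-2.04) and Cd74 (-1.33), with a camera adjusted p of 0.00061 and adjusted p = 0.55 with an estimated correlation. None of the 4 was called without young sham 3 (-0.86 to -1.18), young IR 1 or young IR 3, H2-Aa was the 1 called without young IR 2, and Cd74 was not called without young sham 2 (adjusted p = 0.0621). Of the other named genes Cxcl9 stayed called without each single library. Gbp5, Gbp3, Gbp4, Cd274, Tgtp1 and Tgtp2 did not without young sham 3, where they were at -0.84 to -1.45. With changes that stayed as large (-2.12 to -3.58) they were not called without young IR 3, the same held without young IR 2 for all but Tgtp2, and Cd274 was not called without young IR 1 (adjusted p 0.053 to 0.179).

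**Figure D2:**
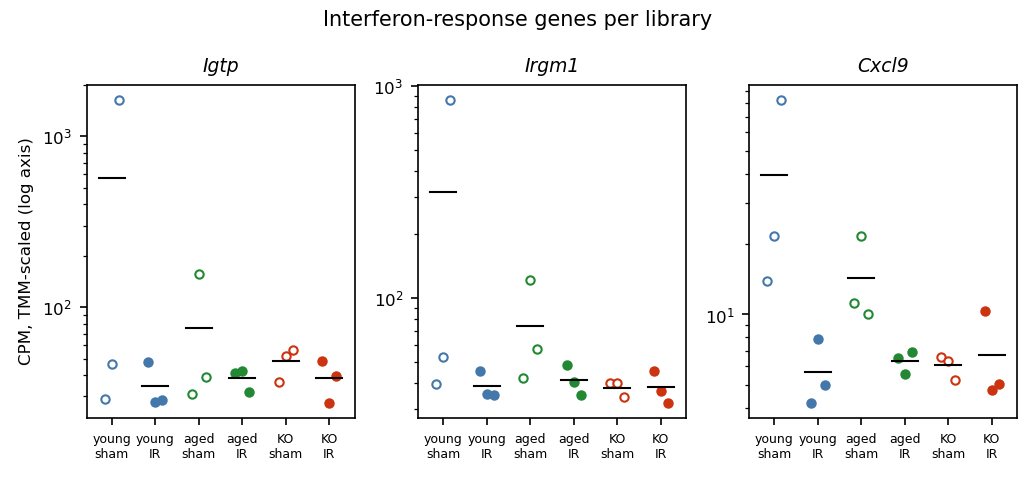
CPM (TMM-scaled, log axes) of the interferon-response genes Igtp, Irgm1 and Cxcl9 in each library, by group (open points sham, filled points IR, bars means of 3). Young sham 3 stands above the other libraries, at 1640 CPM for Igtp and 863 CPM for Irgm1.

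Aged WT hearts raised many inflammatory genes after IR as well. Arg1, a macrophage arginase gene, had 1 count in aged sham hearts and 1194 after IR, a ratio of 1360 with a counting interval of 243 to 53700. Spp1 rose from 1.28 ± 0.533 to 187 ± 102 CPM (SD, n = 3 each), Lcn2 from 4.12 ± 2.94 to 339 ± 174 CPM, and the serum amyloid gene Saa3 from 0.273 to 12.6 ± 5.08 CPM. Log2 fold changes were 7.16 ± 0.65 for Spp1 (adjusted p = 3.15e-05), 6.34 ± 0.73 for Lcn2 (adjusted p = 0.00019), 5.41 ± 0.61 for Saa3 (adjusted p = 0.000161), 5.47 for Cxcl5 (adjusted p = 0.000619) and 5.49 for Chil3 (adjusted p = 0.000787). Trem1 had 2 and 73 counts, a ratio of 41.5 with a counting interval of 11.1 to 349. Ankrd2, a muscle stress gene, rose by 5.07 on the log2 scale (adjusted p = 0.00643). The test called 1054 genes, 743 higher and 311 lower. Leaving out aged sham 1, aged sham 3, aged IR 1 and aged IR 3 in turn gave 236, 442, 260 and 600 genes. Limma voom with quality weights called 3436 genes; with the length trend as a covariate edgeR called 2116, and without the 6 length-tilted libraries 106, with 13 of the 33 called genes named for this comparison, among them Spp1, Arg1, Mmp3 and Timp1.

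By list, 15 of 16 neutrophil markers rose in aged WT hearts (15 adjusted over the list alone), with S100a8 at 4.14 and Slfn4 at 4.31, a camera adjusted p of 1.5e-21 and adjusted p = 0.061 with an estimated correlation. Acute cytokine and chemokine genes rose in 19 of 32 (24 adjusted over the list alone), with Ptx3 at 4.94 ± 0.43, Ccl7 at 3.52 and Ccl2 at 3.41 ± 0.34. Their camera adjusted p was 1.5e-21, and adjusted p = 0.061 with an estimated correlation. Of 34 fibrillar matrix genes 19 rose and 1 fell (23 and 1 adjusted over the list alone), among them Mmp3 (3.10 ± 0.27), Timp1 (4.90 ± 0.50), Lox (2.76) and Thbs1 (2.84). The matrix list had a camera adjusted p of 1.1e-12 and adjusted p = 0.31 with an estimated correlation. Monocyte and macrophage markers rose in 11 of 28 (14 adjusted over the list alone), with Msr1 at 1.99, a camera adjusted p of 6.6e-11 and adjusted p = 0.31 with an estimated correlation. Integrated stress response genes rose in 12 of 32 (21 rose and 1 fell adjusted over the list alone), with Psat1 at 1.86, Creld2 at 1.19 and Xbp1 at 0.87. For these, camera gave 6.5e-07, and adjusted p = 0.31 with an estimated correlation. On the first principal component aged IR 2 lay at 4.6, against 31.6 and 27.2 for aged IR 1 and 3. Without aged sham 1, aged sham 3 and aged IR 1 the risen matrix genes numbered 6, 11 and 7, and the monocyte and macrophage markers 6, 7 and 7. Stress response genes numbered 3, 5 and 7 without these libraries and 6 without aged IR 3.

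Of 40 ribosomal protein genes Rpl3 rose in aged WT hearts (0.87, adjusted p = 0.0364) and 0 rose adjusted over the list alone; the median was 0.45, with a camera adjusted p of 2.4e-10 and adjusted p = 0.58 with an estimated correlation. Mybpc3 (-0.62) and Myh6 (-0.59) fell among 31 contraction genes (4 fell adjusted over the list alone), with a camera adjusted p of 0.0068 and adjusted p = 0.31 with an estimated correlation. Among genes that fell were Pla2g2d (-2.56), Fmod (-2.36), Clcn1 (-2.36), Kcnc1 (-2.25), Tmem52 (-2.17), Olfr78 (-2.11), Lgi3 (-2.00) and Cd247 (-2.00), with adjusted p-values of 0.00233 to 0.0372. The mean log2 CPM of the ribosomal protein genes was 7.58, 7.95 and 7.91 in aged sham 1, 2 and 3 and 8.38, 8.37 and 8.05 in aged IR 1, 2 and 3, lowest in each group in its length-tilted library. Adjusted over the list alone 27 and 37 rose without aged sham 2 and aged IR 3. Rpl3 was not called with upper quartile scaling (adjusted p = 0.0514) or the length trend as a covariate, where the list's median was 0.19. Nor was it called without aged sham 1 or 3 or aged IR 1 or 3, and the same held for Myh6 without any library but aged IR 2, and Mybpc3 and Cd247 without aged IR 1. The call was also lost for Fmod without aged sham 1 or aged IR 1, Kcnc1 without aged IR 3, Tmem52 without aged sham 1 or 2 or aged IR 1 or 3, and Olfr78 without aged sham 3 or aged IR 3 (adjusted p 0.0515 to 0.183 over these losses). Between aged and young WT the IR effects had a correlation across genes of r = 0.83 (Spearman's rho 0.75; genes are not independent replicates), and 834 of the 841 genes called in young WT had the same sign in aged WT.

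**Figure D3:**
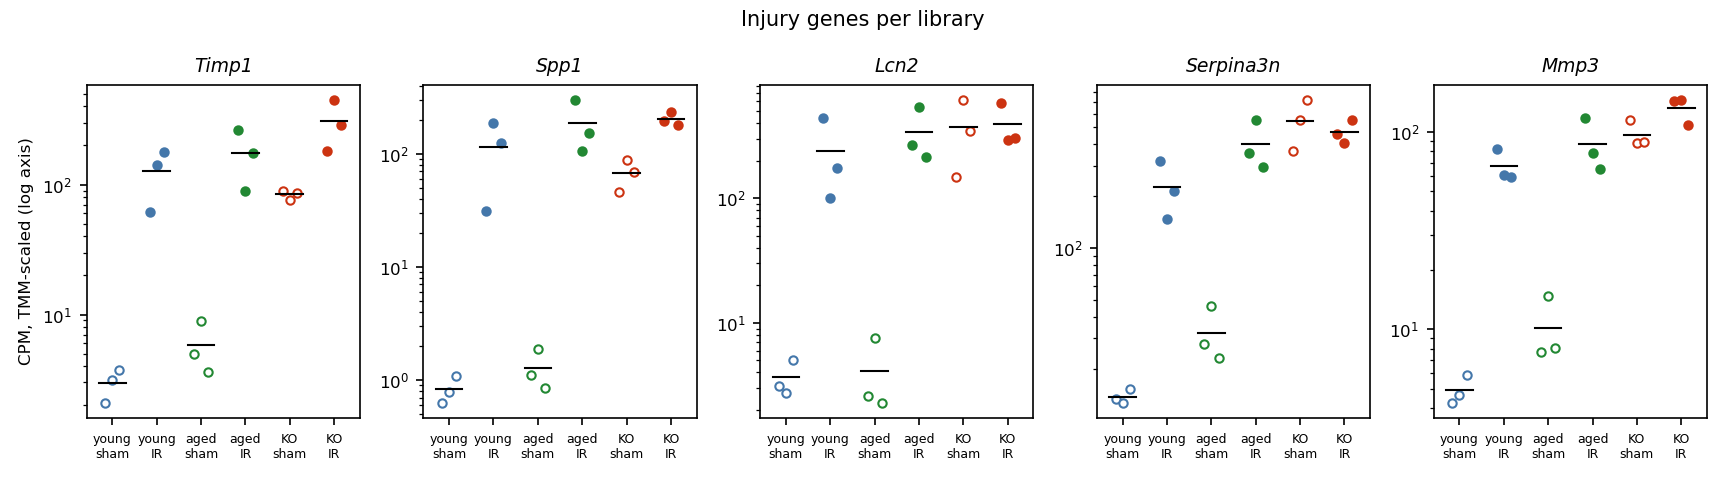
CPM (TMM-scaled, log axes) of Timp1, Spp1, Lcn2, Serpina3n and Mmp3 in each library, by group (open points sham, filled points IR, bars means of 3). The Sesn2-KO sham libraries lie above all WT sham libraries for each gene.

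In Sesn2-KO hearts 0 genes were called between IR and sham by edgeR, with 2037 genes at an unadjusted p below 0.05 and a smallest adjusted p of 0.197. DESeq2's Wald test called 140 genes and limma voom with quality weights 1233. Timp1 was at 84.1 ± 6.64 CPM in sham and 306 ± 136 CPM in IR hearts (SD, n = 3 each), a log2 fold change of 1.86 ± 0.42 (adjusted p = 0.197), and Spp1 at 67.7 ± 20.8 and 204 ± 30.1 CPM, a change of 1.59 ± 0.47 (adjusted p = 0.202). Arg1 was at 2.60 ± 0.57 (adjusted p = 0.197), Tnc at 2.26 (adjusted p = 0.219) and Ccl2 at 1.39 (adjusted p = 0.197). The heparan sulfate proteoglycan gene Sdc1 had the smallest p (1.26 ± 0.22, adjusted p = 0.197), and it was the 1 gene called when Sesn2-KO IR 1 was left out. Sdc1 falls outside the rule for named genes and was chosen after its values were seen.

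In Sesn2-KO 0 list members were called between IR and sham over all genes, and fry, which tests a list by itself, called 0 of 41 lists. Camera with its preset correlation, which sets a list against the other genes, called 11 lists higher and 6 lower. Of 32 cytokine and chemokine genes, 13 were higher adjusted over the list alone (median 1.03, camera adjusted p = 1.4e-10, adjusted p = 0.47 with an estimated correlation), and of 16 neutrophil markers 9 (median 1.17, camera adjusted p = 1.5e-08, adjusted p = 0.47 with an estimated correlation). Fibrillar matrix genes had 11 of 34 higher adjusted over the list alone (camera adjusted p = 1.6e-09, adjusted p = 0.48 with an estimated correlation). All 32 fatty acid oxidation genes had log2 fold changes below 0, with a median of -0.44 and 0 lower adjusted over the list alone; Acadm was at -0.45 and Hadhb at -0.40. Camera gave an adjusted p of 1.4e-10 for fatty acid oxidation, and adjusted p = 0.49 with an estimated correlation. The 21 TCA cycle genes had a median of -0.27 and 0 lower adjusted over the list alone (camera adjusted p = 1.1e-08, adjusted p = 0.49 with an estimated correlation), with Ogdh at -0.49 and Suclg2 at -0.36. Adjusted over the list alone, cytokine genes numbered 3 without Sesn2-KO sham 1 and 6 without Sesn2-KO sham 2 or Sesn2-KO IR 2 or 3, and neutrophil markers 5 and 4 without Sesn2-KO sham 2 and Sesn2-KO IR 2. Matrix genes numbered 6, 3 and 19 without Sesn2-KO sham 1, 2 and 3 and 0 and 5 without Sesn2-KO IR 2 and 3. Lower fatty acid oxidation genes numbered 5 without Sesn2-KO sham 1 and 17 without Sesn2-KO IR 1, and lower TCA cycle genes 10 without Sesn2-KO sham 1. The IR effects in Sesn2-KO and young WT had a correlation across genes of r = 0.57 with a slope of 0.35, and 778 of the 841 genes called in young WT had the same sign.

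**Figure D4:**
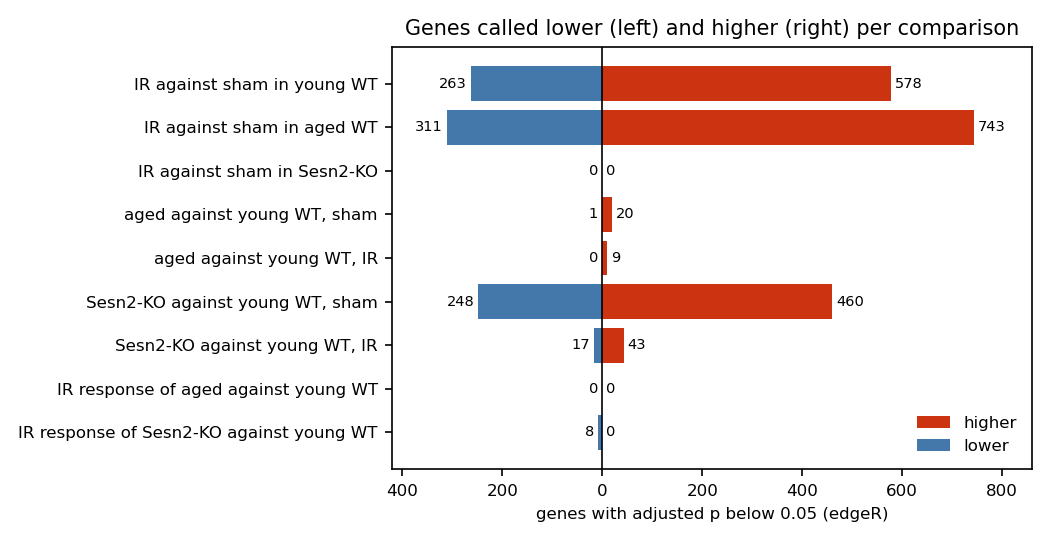
Bars show the number of genes with an adjusted p below 0.05 (edgeR) that were higher (right) or lower (left) in each of the 9 comparisons, on 1 axis of gene counts from 0. IR against sham called 841 genes in young WT, 1054 in aged WT and 0 in Sesn2-KO.

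Aged sham hearts differed from young sham hearts in 21 genes, 20 higher and 1 lower. The cytochrome P450 gene Cyp2b10 rose from 0.572 ± 0.25 to 9.87 ± 5.21 CPM (SD, n = 3 each), the cadherin gene Cdh22 (chromosome 2, 165111507 to 165234853) from 1.54 ± 0.31 to 12 ± 2.98 CPM, and Ano5 from 4.39 ± 1.3 to 23.8 ± 6.91 CPM. Slc38a1, an amino acid transporter gene, fell from 17.1 ± 2.48 to 5.62 ± 0.59 CPM. The log2 fold changes were 4.07 ± 0.51 for Cyp2b10 (adjusted p = 0.00241), 2.97 ± 0.30 for Cdh22 (adjusted p = 0.000471), 2.43 ± 0.26 for Ano5 (adjusted p = 0.000475) and -1.60 ± 0.25 for Slc38a1 (adjusted p = 0.0108). The macrophage lectin gene Cd209f (3.31 ± 0.57, adjusted p = 0.0228) and the potassium channel genes Kcnk1 (3.45, adjusted p = 0.0308) and Kcnc1 (2.75, adjusted p = 0.0349) also rose. So did Amtn (3.38, adjusted p = 0.0108) and Ryr1, the skeletal muscle ryanodine receptor gene (2.18 ± 0.32, adjusted p = 0.00775). Cyp2b10, Cdh22 and Ano5 stayed called without each of the 6 libraries. Cd209f and Kcnc1 were not called without any 1 of them, and Kcnk1 and Amtn without any but aged sham 3. Slc38a1 was not called without young sham 1 or 3 or aged sham 2 or 3, nor Ryr1 without young sham 3 or aged sham 2 (adjusted p 0.0514 to 0.241 over these losses). The count of 21 was 8, 9 and 4 without young sham 1, 2 and 3, and 14, 7 and 13 without aged sham 1, 2 and 3. It was 44 by DESeq2's Wald test, 184 by limma voom with quality weights, 40 with the length trend as a covariate and 1 (Abat) without the 6 length-tilted libraries. With the 6 sham libraries of the compared groups alone in the fit, 11 of the 21 genes stayed called, and Kcnk1, Ryr1, Abat and Ccl11 of the named genes were not called.

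By list, 0 of the 41 lists were called between aged and young sham hearts by fry or by camera with an estimated correlation, and 10 were higher by camera with its preset correlation. Of 10 T and NK cell markers, 6 were higher adjusted over the list alone, with a median of 1.71, a camera adjusted p of 1.8e-07 and adjusted p = 0.32 with an estimated correlation; Ccl5 was at 2.12 ± 0.58 and Cd3g at 2.04 ± 0.62. Of 24 senescence genes, 6 were higher adjusted over the list alone, with a camera adjusted p of 2.9e-05 and adjusted p = 0.32 with an estimated correlation. Cdkn2a, the p16 gene, was at 0.254 ± 0.0206 CPM in young and 1.27 ± 0.519 CPM in aged sham hearts (SD, n = 3 each; log2 fold change 2.26 ± 0.54, adjusted p = 0.22). The 23 complement and coagulation genes had a median of 0.24 and 0 higher adjusted over the list alone (camera adjusted p = 1.1e-05, adjusted p = 0.52 with an estimated correlation), with C7 at 0.86 ± 0.24. The 30 NRF2 genes had 1 higher adjusted over the list alone (camera adjusted p = 0.00058, adjusted p = 0.33 with an estimated correlation), with Gsta1 at 1.52 ± 0.39 (adjusted p = 0.307). The interferon list was not called (median -0.33, camera adjusted p = 0.055, 0 adjusted over the list alone). Its median was -0.61, -0.54 and -0.77 without young sham 1, young sham 2 and aged sham 2 (camera adjusted p = 2.3e-09, 3.9e-05 and 9.2e-08) and 0.49, in the other direction, without young sham 3 (8.5e-10). Aged sham 2 stood apart from aged sham 1 and 3, with a mean log2 CPM of 0.87 against -0.19 and -0.40 for T and NK cell markers, and of 5.35 against 4.64 and 4.72 for complement and coagulation genes. Without aged sham 2 the T and NK list had a median of 1.21 and a camera adjusted p of 0.003, the senescence list a median of 0.13 and 0.0088, and the complement list a median of 0.03 and 0.12. Adjusted over the list alone, T and NK cell markers numbered 0 without young sham 1 or aged sham 2, and senescence genes 0 without young sham 1 or 2 or aged sham 2. Complement genes numbered 1, 6 and 5 without young sham 2, aged sham 1 and aged sham 3, and NRF2 genes 0 to 2 without single libraries.

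After IR, 9 genes were higher in aged than in young WT hearts and 0 were lower. Cd209f was at 7.69 ± 5.08 CPM in aged and 0.244 CPM in young IR hearts (SD, n = 3), and Ccl11, the eosinophil chemokine eotaxin, at 18.8 ± 1.43 and 5.48 ± 1.35 CPM. Log2 fold changes were 4.87 ± 0.65 for Cd209f (adjusted p = 0.00915), 1.78 ± 0.20 for Ccl11 (adjusted p = 0.00133), and 3.27 for Cyp2b10, 1.86 for Cdh22 and 1.33 for Ric3 (each adjusted p = 0.0166). They were 1.81 for Ano5 (adjusted p = 0.0139), 1.74 for Fam169a (adjusted p = 0.033) and 1.46 for Cdh4 (adjusted p = 0.0254). All 9 genes were also called between aged and young sham hearts. Il33, an alarmin gene, was at 47.4 CPM in aged and 19.7 CPM in young IR hearts (log2 fold change 1.26 ± 0.23, adjusted p = 0.0605), and was called without aged IR 3 (1.46, adjusted p = 0.017). Complement and coagulation genes had 0 of 23 called and 5 higher adjusted over the list alone, with C7 at 0.93 and C3 at 1.04 (camera adjusted p = 5.9e-08, adjusted p = 0.47 with an estimated correlation). NRF2 genes had a median of 0.20 and 1 higher adjusted over the list alone (camera adjusted p = 1.1e-05, adjusted p = 0.30 with an estimated correlation). Neutrophil markers had 2 of 16 higher adjusted over the list alone (median 0.64, camera adjusted p = 2.2e-05, adjusted p = 0.55 with an estimated correlation). By fry 0 of 41 lists were called. Adjusted over the list alone, complement genes numbered 0 without young IR 2 or 3 or aged IR 2 and 1 without aged IR 1, and neutrophil markers 0 without young IR 1 or 2 or aged IR 1 and 1 without aged IR 2. NRF2 genes numbered 7 and 3 without young IR 1 and aged IR 3 and 0 without any of the other 4 libraries. Ccl11 stayed called without each of the 6 libraries and was the 1 gene called without young IR 2 or 3, and Ccl11 and Cd209f were the genes called without aged IR 2. Of the named genes Cdh4 was not called without young IR 1, Ric3 and Fam169a without aged IR 1, and Cdh22, Cdh4 and Fam169a without aged IR 3 (adjusted p 0.0521 to 0.315 over these losses). The count of 9 was 17 without young IR 1, 6 without aged IR 1 and 12 without aged IR 3. It was 33 by DESeq2's Wald test, 18 by limma voom with quality weights, 0 with the 6 IR libraries alone in the fit and 3, with Cd209f and Ccl11 among them, without the 6 length-tilted libraries.

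Sham hearts of Sesn2-KO mice had higher levels than young WT sham hearts of 235 of the 743 genes that rose after IR in aged WT. Lcn2 was at 372 ± 236 CPM, against 3.65 ± 1.24 CPM in young WT sham hearts (SD, n = 3 each), Spp1 at 67.7 ± 20.8 against 0.831 ± 0.231 CPM, and Mmp3 at 97.2 ± 15.6 against 4.93 ± 0.869 CPM. The acute-phase serpin gene Serpina3n (chromosome 12, 104406729 to 104414329) was at 546 ± 179 against 13.7 ± 1.33 CPM. Log2 fold changes were 6.67 ± 0.75 for Lcn2 (adjusted p = 0.000111), 6.35 ± 0.67 for Spp1 (adjusted p = 6.82e-05), 4.30 ± 0.29 for Mmp3 (adjusted p = 1.11e-06), 5.31 ± 0.38 for Serpina3n (adjusted p = 1.26e-06) and 5.73 ± 0.67 for Saa3 (adjusted p = 0.000179). Arg1 rose by 6.32 ± 1.06 (adjusted p = 0.00271) and Sprr1a by 5.64 (adjusted p = 0.00337). Serpina3m had 2 counts in young WT and 317 in Sesn2-KO sham hearts, a ratio of 152 with a counting interval of 41.8 to 1260. Cxcl13, a B cell chemokine gene, had 2 and 225 counts, a ratio of 108 (29.6 to 898), and was not called without young sham 1 (adjusted p = 0.0579). Across genes, these fold changes and those of IR in aged WT, which share no library, had r = 0.65 (rho 0.58), and 629 of the 708 genes called here had the same sign there. Of the 708, 460 were higher and 248 lower. Their number was 338, 456 and 296 without young sham 1, 2 and 3, and 360, 370 and 456 without Sesn2-KO sham 1, 2 and 3. It was 1112 by DESeq2's Wald test, 2179 by limma voom with quality weights, 1678 with the length trend as a covariate and 144 without the 6 length-tilted libraries. Of the 65 called genes named for this comparison 30 stayed called without the length-tilted libraries, among them Lcn2, Spp1, Mmp3, Serpina3n, Saa3, Il33, Ptx3 and Hmox1.

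Many inflammatory genes were higher in Sesn2-KO sham hearts. Of 32 cytokine and chemokine genes 17 rose (18 adjusted over the list alone), including Il33 (2.53 ± 0.24), Ptx3 (3.62) and Ccl2 (2.09), with a camera adjusted p of 9.1e-20 and adjusted p = 0.069 with an estimated correlation. Neutrophil markers rose in 12 of 16 (14 adjusted over the list alone), such as Clec4d (3.85) and S100a8 (3.72), with a camera adjusted p of 1.6e-16 and adjusted p = 0.069 with an estimated correlation. Monocyte and macrophage markers rose in 11 of 28 (20 adjusted over the list alone), with F13a1 at 0.96 and Mrc1 at 0.84 (camera adjusted p = 1.4e-12, adjusted p = 0.19 with an estimated correlation). Complement and coagulation genes rose in 10 of 23 (19 rose and 1 fell adjusted over the list alone), with C7 at 1.75 and C5ar1 at 1.34 (camera adjusted p = 7.8e-11, adjusted p = 0.098 with an estimated correlation). Senescence genes rose in 9 of 24 (13 adjusted over the list alone), among them Edn3 (2.93) and Mmp3, with a camera adjusted p of 2.6e-09 and adjusted p = 0.069 with an estimated correlation. T and NK cell markers rose in 3 of 10 (6 adjusted over the list alone; camera adjusted p = 0.0023, adjusted p = 0.37 with an estimated correlation): Cd3g (2.41), Ccl5 (2.15) and Cd3d (2 against 34 counts, a ratio of 16.3 with a counting interval of 4.19 to 140). None of these 3 was called without any 1 library but Sesn2-KO sham 3. The risen neutrophil markers numbered 6, 7 and 6 without young sham 1, 2 and 3 and 7 without Sesn2-KO sham 1. Monocyte markers numbered 7 without young sham 1, young sham 2 or Sesn2-KO sham 1, and senescence genes 5 without young sham 1. Complement genes numbered 3, 6 and 5 without young sham 1, 2 and 3 and 4 and 6 without Sesn2-KO sham 1 and 2.

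Some stress and matrix genes were also higher in Sesn2-KO sham hearts. Fibrillar matrix genes rose in 7 of 34 and fell in 1 (9 and 1 adjusted over the list alone), with Timp1 at 4.82 ± 0.52, a camera adjusted p of 6.9e-07 and adjusted p = 0.36 with an estimated correlation. Immediate early genes rose in 8 of 28 (12 adjusted over the list alone), with Junb at 1.45 and Myc at 1.88 (camera adjusted p = 5.5e-08, adjusted p = 0.16 with an estimated correlation). Of 32 integrated stress response genes 10 rose, with Mthfd2 at 1.59, and Sesn2 itself fell (17 and 1 adjusted over the list alone; camera adjusted p = 1.1e-07, adjusted p = 0.19 with an estimated correlation). NRF2 genes rose in 4 of 30 (7 adjusted over the list alone), led by Hmox1 (2.18 ± 0.22, adjusted p = 3.91e-05), with a camera adjusted p of 7.8e-06 and adjusted p = 0.098 with an estimated correlation. Of 36 sestrin, AMPK and mTORC1 regulators Sesn2 was the 1 called (4 fell adjusted over the list alone; median -0.02, camera adjusted p = 0.28), with 2 called without young sham 2 or Sesn2-KO sham 2 or 3. The risen matrix genes numbered 3, 4 and 2 without young sham 1, 2 and 3 and 4 without Sesn2-KO sham 3, and the immediate early genes 3 without young sham 3 and 5 without Sesn2-KO sham 2 or 3. The NRF2 genes numbered 1, 2 and 1 without young sham 1, 2 and 3 and 1 without Sesn2-KO sham 1 or 2. The integrated stress response genes numbered 1, 1 and 2 without young sham 1, 2 and 3, and 1, 5 and 3 without Sesn2-KO sham 1, 2 and 3.

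Among genes that were lower in Sesn2-KO sham hearts, Pydc3 fell by 5.53 ± 0.51 on the log2 scale (adjusted p = 2.44e-05), from 5.03 ± 2.38 to 0.0986 ± 0.0437 CPM (SD, n = 3 each), and Ddc, the aromatic amino acid decarboxylase gene, fell by 2.95 ± 0.47 (adjusted p = 0.00211). Pydc3 has close paralogues, so its counts are uncertain. Mesothelial and epicardial markers went both ways. Of 13, Upk3b (-4.15) and Bnc1 fell, the latter with 41 counts in young WT and 1 in Sesn2-KO, a ratio of 42.6 with a counting interval of 7.24 to 1730. Aldh1a2 (2.21) and C3 (1.19) rose (2 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.025, adjusted p = 0.59 with an estimated correlation). The endothelial genes Kdr (-0.73 ± 0.12, adjusted p = 0.00253) and Erg (-0.44) fell, 2 of 21 (2 adjusted over the list alone; camera adjusted p = 0.0045, adjusted p = 0.63 with an estimated correlation). So did Smtn (-0.63) and Abcc9 (-0.72), 2 of 16 smooth muscle and pericyte markers (5 adjusted over the list alone; camera adjusted p = 0.0013, adjusted p = 0.19 with an estimated correlation). Without single libraries, Erg was not called in any of the 6 fits, Abcc9 not without young sham 1 or 3 or Sesn2-KO sham 1 or 2, and Smtn not without young sham 1. Aldh1a2 was not called without young sham 1 or 3 or Sesn2-KO sham 2, C3 not without any but young sham 2, and Upk3b and Bnc1 not without any but young sham 1 (adjusted p 0.0503 to 0.171). Camera's adjusted p rose to 0.23, 0.066 and 0.068 for the mesothelial list without young sham 2 and Sesn2-KO sham 2 and 3, and to 0.093 and 0.2 for the endothelial list without young sham 2 and Sesn2-KO sham 3; the endothelial list was at 0.1 without the 6 length-tilted libraries.

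Of 40 interferon genes, 9 were lower in Sesn2-KO sham hearts, among them Rsad2 (-1.67) and Cxcl9 (-2.69), with a median of -1.21 (29 fell adjusted over the list alone; camera adjusted p = 5.6e-10, adjusted p = 0.47 with an estimated correlation). Without young sham 3, where these genes were high, 2 fell, the median was -0.27 and the camera adjusted p was 0.0043. The number was 17 without young sham 1 or 2, and 2 without Sesn2-KO sham 1, 2 or 3. Outside the list, Cd274 (-3.14), Gbp4 (-2.96), Tgtp1 (-2.79) and Cybrd1 (-2.82) also fell. Cd274 and Tgtp1 were at -0.74 and -1.21, not called, without young sham 3, and at -2.67 to -3.32, not called, without Sesn2-KO sham 1, 2 or 3; Cybrd1 was not called without any but young sham 1 (adjusted p 0.0663 to 0.349).

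After IR, 60 genes differed between Sesn2-KO and young WT hearts, 43 higher and 17 lower, and 48 of them were also called between the sham groups. Hmgn2, a nucleosome-binding protein gene on the same chromosome as Sesn2 (chromosome 4, 133964738 to 133968650), was at 25.4 ± 3.06 CPM in Sesn2-KO and 83.8 ± 22.6 CPM in young WT (SD, n = 3 each; log2 fold change -1.72 ± 0.21, adjusted p = 0.00154). Il33 was at 55.1 ± 6.22 and 19.7 CPM (1.48 ± 0.23, adjusted p = 0.00843), and Edn3 at 20.4 ± 11.6 and 1.55 CPM (3.74 ± 0.61, adjusted p = 0.00994). Also higher were Ppp2r2c (4.04, adjusted p = 0.0092), Nkain2 (2.56, adjusted p = 0.00994), Cacna2d3 (3.08, adjusted p = 0.0145), Cd209f (3.38, adjusted p = 0.0448), Cyp2b10 (2.53, adjusted p = 0.0377) and Ryr1 (2.20 ± 0.32, adjusted p = 0.0061). Lower, besides Sesn2 and Ide, were Pydc3 (-2.77), Ddc (-2.56), Rasl10a (-1.89), Hpn (-1.54) and Car14 (-1.05). Lcn2 was not called, at 394 ± 163 CPM in Sesn2-KO and 239 ± 179 CPM in young WT, nor was Spp1, at 204 ± 30.1 and 114 ± 77.8 CPM. Hmgn2 and Ryr1 stayed called without each of the 6 libraries. Il33, Nkain2 and Cacna2d3 were not called without young IR 2, Edn3 and Ppp2r2c without young IR 1 or 2, Hpn without young IR 1 or Sesn2-KO IR 2, and Pydc3 without young IR 2 or Sesn2-KO IR 2. The same held for Ddc and Car14 without young IR 1 or 2 or Sesn2-KO IR 2 or 3, Cyp2b10 without young IR 2 or 3 or Sesn2-KO IR 2 or 3, Rasl10a without any but young IR 3, and Cd209f without any but Sesn2-KO IR 3 (adjusted p 0.0512 to 0.216 over these losses). The count of 60 was 24 without young IR 1, 9 without young IR 2, 97 without Sesn2-KO IR 1 and 27 without Sesn2-KO IR 2. It was 258 by DESeq2's Wald test, of which 50% were higher against 71.7% here (48.6% to 85.2% without single libraries), 229 by limma voom with quality weights, and 4 with the 6 IR libraries of these groups alone in the fit. With the length trend as a covariate it was 192 (53.6% higher). Without the 6 length-tilted libraries it was 55, of which 41.8% were higher, with 10 of the 20 named called genes. Wdfy1 and Ide were the named genes called with the 6 IR libraries alone, where Sesn2 was at -3.98 (adjusted p = 0.078).

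By list, 9 of 23 complement and coagulation genes were higher adjusted over the list alone in Sesn2-KO IR hearts and 0 were called over all genes, with C7 at 1.13 ± 0.24 (camera adjusted p = 1.4e-08, adjusted p = 0.35 with an estimated correlation). Edn3 was the 1 called of 24 senescence genes (10 higher adjusted over the list alone; camera adjusted p = 1.6e-05, adjusted p = 0.35 with an estimated correlation). Cd3g (3.30) was the 1 called of 10 T and NK cell markers (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0001, adjusted p = 0.35 with an estimated correlation). The 21 TCA cycle genes had a median of -0.28 with 3 lower adjusted over the list alone, such as Cs, the citrate synthase gene (-0.46 ± 0.13, adjusted p = 0.139). Camera's adjusted p for the TCA list was 1.4e-08, and adjusted p = 0.35 with an estimated correlation. The 32 fatty acid oxidation genes had a median of -0.29 and 0 lower adjusted over the list alone (camera adjusted p = 2e-05, adjusted p = 0.47 with an estimated correlation), and without young IR 1 a median of -0.04 and a camera adjusted p of 0.32. Of 17 atrial and conduction markers Fgf12 rose (4.57 ± 0.84, adjusted p = 0.0254) and 7 were higher adjusted over the list alone (camera adjusted p = 0.0013, adjusted p = 0.35 with an estimated correlation). The atrial light chain gene Myl7 was at 252 CPM in Sesn2-KO IR 1 and at 0.483 and 37.3 CPM in replicates 2 and 3, against 0.094 to 1.71 CPM in young IR and 4.66 to 36.7 CPM in young sham hearts. The list's mean log2 CPM was 3.13 to 3.2 in young IR, 3.55 to 4.39 in young sham and 3.53 to 5.24 in Sesn2-KO IR libraries, and it was not called after IR in young WT (camera adjusted p = 0.22). Without Sesn2-KO IR 1 the atrial list's camera adjusted p was 0.051, against 0.063 without the 6 length-tilted libraries. Fgf12 was not called without young IR 1, 2 or 3, Edn3 not without young IR 1 or 2, and Cd3g not without any library but Sesn2-KO IR 3 (adjusted p 0.0643 to 0.172). Called senescence genes numbered 2 without young IR 3 or Sesn2-KO IR 1, and called atrial markers 3 without Sesn2-KO IR 2. Adjusted over the list alone, complement genes numbered 2 and 4 without young IR 2 and 3, senescence genes 6 without young IR 1 or Sesn2-KO IR 2, and atrial markers 3 without Sesn2-KO IR 1. Higher T and NK cell markers numbered 2 without young IR 1 or Sesn2-KO IR 1 and 1 without young IR 3 or Sesn2-KO IR 2. Lower TCA cycle genes numbered 0 without young IR 1 or Sesn2-KO IR 2, and 15, 8 and 5 without young IR 3, Sesn2-KO IR 1 and Sesn2-KO IR 3. By fry 0 of 41 lists were called.

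The IR response was smaller in Sesn2-KO than in young WT for 8 genes, tested as an interaction. These were Serpina3n (difference of log2 fold changes -4.26 ± 0.46) and Mmp3 (-3.32 ± 0.37), both with adjusted p = 0.000711, and Lcn2 (-5.95 ± 0.89, adjusted p = 0.0121). The others were Saa3 (-5.67 ± 0.83) and Spp1 (-5.51 ± 0.81), both with adjusted p = 0.0119, Clec4d (-3.35 ± 0.47, adjusted p = 0.0111), Ptx3 (-3.33 ± 0.54, adjusted p = 0.0242) and Hmox1 (-1.78 ± 0.29, adjusted p = 0.0287). Each was called higher in Sesn2-KO than in young WT sham hearts: Ptx3 was at 7.97 ± 3.6 CPM there, 16.4 ± 3.92 CPM in Sesn2-KO IR, 0.642 ± 0.129 CPM in young sham and 13.5 ± 4.3 CPM in young IR hearts (SD, n = 3 each). Timp1 (-3.55 ± 0.65, adjusted p = 0.0792) and Ccl2 (-2.06, adjusted p = 0.188) were not called. Serpina3n and Mmp3 stayed called without each of the 12 libraries. Lcn2, Saa3 and Spp1 were not called without young sham 1, 2 or 3, Clec4d without young sham 1 or 3, and Lcn2 also without Sesn2-KO IR 2 or 3. Hmox1 was not called without any but young IR 1 or Sesn2-KO sham 1, and Ptx3 not without any but those or Sesn2-KO IR 3 (adjusted p 0.0534 to 0.164 over these losses). Without young IR 1, Timp1 (adjusted p = 0.0119) and Ccl2 (adjusted p = 0.0499) were called. The count of 8 was 2, 3 and 2 without young sham 1, 2 and 3, 16 without young IR 1 and 5 without Sesn2-KO IR 2. It was 30 by DESeq2's Wald test, 13 by limma voom with quality weights and 0 without the 6 length-tilted libraries. Ptx3 and Hmox1 were not called with these 12 libraries alone in the fit.

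By list, a few inflammatory genes had smaller IR responses in Sesn2-KO, and fry called 0 of 41 lists. Of 16 neutrophil markers, 2 had a smaller response and 10 adjusted over the list alone (median -2.98, camera adjusted p = 5.4e-14, adjusted p = 0.32 with an estimated correlation). Of 32 cytokine and chemokine genes, 3 had a smaller response and 13 adjusted over the list alone (median -0.88, camera adjusted p = 9.1e-13, adjusted p = 0.32 with an estimated correlation). Monocyte and macrophage markers (1 of 28, and 7 adjusted over the list alone) and fibrillar matrix genes (1 of 34, and 2 adjusted over the list alone) had camera adjusted p-values of 1.8e-07 and 1.8e-06, each with adjusted p = 0.40 with an estimated correlation. The 2 neutrophil markers, Lcn2 and Clec4d, numbered 0, 1 and 0 without young sham 1, 2 and 3 and 1 without Sesn2-KO IR 2 or 3. The 3 cytokine genes, Lcn2, Saa3 and Ptx3, numbered 0 without any 1 young sham library, 7 without young IR 1 and 1 without Sesn2-KO IR 2. The 1 monocyte and macrophage marker, Spp1, was lost without any 1 young sham library, and matrix genes numbered 2 without young IR 1. Adjusted over the list alone, matrix genes numbered 20 and 5 without young IR 1 and young sham 2, and monocyte and macrophage markers 2 without young sham 1. Without the 6 length-tilted libraries the neutrophil, cytokine, monocyte and matrix lists had 2, 3, 0 and 1 adjusted over the list alone, and the monocyte list a camera adjusted p of 0.05.

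Between aged and young WT, 0 genes had a different IR response by edgeR's quasi-likelihood test, with 152 genes at an unadjusted p below 0.05; DESeq2's Wald test and limma voom with quality weights also called 0. Clec4d was at -1.62 ± 0.50 (adjusted p = 1) and Postn, the periostin gene, at -1.66 ± 0.76 (adjusted p = 1). In simulated counts edgeR recovered 78% of 4-fold and 35.4% of 2-fold differences, which may overstate power in real hearts. Fry called 0 of 41 lists. By camera with its preset correlation the 40 ribosomal protein genes stood higher in aged hearts than the other genes (median 0.29, 0 adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.91 with an estimated correlation), with a camera adjusted p of 0.15 without young sham 2. The 10 T and NK cell markers stood lower (median -0.92, 0 adjusted over the list alone, camera adjusted p = 0.0031, adjusted p = 0.91 with an estimated correlation), with 0.12, 0.15 and 0.31 without young sham 1, young IR 2 and aged sham 2. The 40 interferon genes had a median of 0.52 (0 adjusted over the list alone, camera adjusted p = 0.0065, adjusted p = 0.91 with an estimated correlation). Without young sham 3 their median was -0.34, called in the other direction (camera adjusted p = 6.7e-05). It was not called without young IR 2, aged sham 1 or aged IR 1, nor with the length trend as a covariate (0.15 to 0.99).

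**Figure D5:**
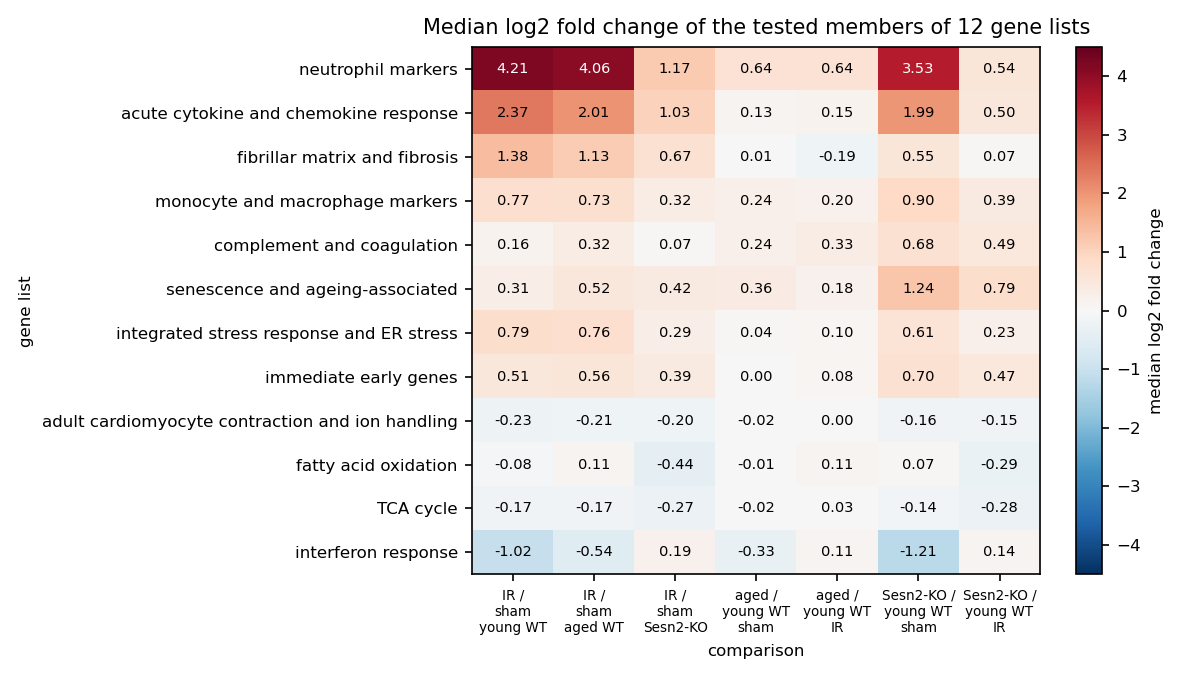
Colour and numbers give the median log2 fold change of the tested members of 12 gene lists (vertical axis) in 7 comparisons (horizontal axis), from blue below 0 to red above 0. Neutrophil markers have medians of 4.21 and 4.06 for IR in young and aged WT and 1.17 for IR in Sesn2-KO.

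Aged WT and Sesn2-KO hearts shared some called genes against young WT, and both groups also differed from young WT in the source of the mice. In sham hearts 17 genes were called in both comparisons, 16 higher and 1 lower. Independent lists would share 0.66 and 0.02, but both comparisons use the same 3 young libraries. Simulated unchanged groups had 0 genes called in both; of as many genes with the smallest p, they had a mean of 12.7 higher (at most 16 in 20 simulations) and 0.55 lower in both. They included Cdh22, Cyp2b10, Ano5, Ryr1, Cd209f, Ccl11 and Abat (higher) and Slc38a1 (lower). Ccl11 was at 6.67 ± 0.911 CPM in young, 14.1 ± 1.65 CPM in aged and 18.8 ± 1.59 CPM in Sesn2-KO sham hearts (SD, n = 3 each). After IR, 8 genes were called higher in both, against 0.03 for independent lists and a simulated mean of 2.35 (at most 5). Across genes fold changes had r = 0.60 and covariance 0.133 in sham hearts, against 0.50 and 0.051 in simulated unchanged groups (covariance difference 0.082). After IR they were 0.65 and 0.104, against 0.50 and 0.049 (difference 0.055). Part or all of this may come from the 3 shared young libraries, which could not be halved. Trends such as young sham 1's length tilt enter both comparisons. The 16 genes higher in both numbered 6, 7 and 4 without young sham 1, 2 and 3 and 6 without aged sham 2, and Slc38a1 was not in both without young sham 1 or 3 or aged sham 2 or 3. Of the named genes, Ccl11 and Cd209f were not called between aged and young sham hearts without any 1 library, Ryr1 not without young sham 3 or aged sham 2, and Abat not without young sham 3 (adjusted p 0.0514 to 0.216). The 8 genes after IR numbered 5, 1 and 1 without young IR 1, 2 and 3, 5 and 2 without aged IR 1 and 2, and 4 and 5 without Sesn2-KO IR 2 and 3.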

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

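Here the tests of why few genes were called between IR and sham in Sesn2-KO, the test of receptor gene counts and the count over 52 of the splits were chosen after the result was seen; the difference of IR responses and the count over other splits of the samples were planned.

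By the test of the difference itself, the IR response was smaller in Sesn2-KO than in young WT for 8 genes. The log2 differences were -4.26 for Serpina3n, -3.32 for Mmp3, -3.35 for Clec4d, -5.67 for Saa3, -5.51 for Spp1, -5.95 for Lcn2, -3.33 for Ptx3 and -1.78 for Hmox1. Of 100 splits of the 12 libraries, the real one included, 9 gave at least 8 genes, so chance cannot be excluded at this count; the highest other split gave 2630 genes. That split kept most sham and IR labels in young WT and exchanged most in Sesn2-KO, so that the IR effect itself enters its count. Of the 52 splits that kept most labels in both or in neither, 5 gave at least 8 genes, and the highest other gave 15. With the length trend as a covariate the count was 8, 7 of them the same (Spp1 was lost) and 1 with a difference above 0, and without the 6 length-tilted libraries it was 0. The count was 2, 3 and 2 without young sham 1, 2 and 3, 16 without young IR 1 and 5 without Sesn2-KO IR 2.

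Between IR and sham in Sesn2-KO, 0 genes were called by edgeR (2037 at unadjusted p below 0.05), 140 by DESeq2 and 1233 by voom. Over the 743 genes called higher after IR in aged WT, the median log2 fold change of IR was 0.78 in young WT and 0.47 in Sesn2-KO, which is 60.4% of the former. This lies between the values set for a wider spread alone (75% or more) and against it (below 60%). As groups share 1 spread per gene in edgeR, a wider spread would not lower calls in Sesn2-KO alone. Over the same genes the median of Sesn2-KO sham against young sham hearts was 0.57, or 73.2% of the IR effect in young WT. The 0.57 is the raised sham level itself and shares young sham hearts with that effect, so it tests no cause. Whether this level comes from loss of Sesn2 or the source of the mice was not tested.

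The 1455 olfactory and vomeronasal receptor genes, outside the comparisons, had a mean of 3.67 CPM of the raw library total in the 6 Sesn2-KO libraries (2.54 to 6.34), above the 1.10 to 2.34 CPM of the 12 WT libraries (two-sided exact permutation p = 5.4e-05 over 18564 splits, the smallest these can give). After thinning each library to 9404531 counts, 16046 to 16723 genes were detected in Sesn2-KO libraries and 15606 to 15856 in WT libraries.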

How the results depend on the processing

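Alternatives were planned, except the length-trend covariate and leaving out the 6 length-tilted libraries. No called gene named in the text and no similarity changed direction under any of them. Of the list tests with camera, 13 were there called against their direction with all libraries. Of the 13, 1 was called with all libraries: the interferon list for the IR response of aged against young WT, at 0.0065 and higher, was at 6.7e-05 and lower without young sham 3, and at 5.7e-10 to 0.99 and higher without other libraries. Another scaling (DESeq2 size factors or upper quartile) kept each count of called genes within 1.5 times, and so did dropping the filter on low counts. The largest shift of the median log2 fold change by another scaling was 0.03. Leaving out a library or the 6 tilted ones also lowers the number of mice per group to 2; apart from that, the cause was not tested.

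The DESeq2 Wald test called 1318 genes for IR in young WT (841 with edgeR), 140 for IR in Sesn2-KO (0), 44 for aged against young sham (21), 33 for aged against young IR (9) and 1112 for Sesn2-KO against young WT sham (708). It called 258 for Sesn2-KO against young WT IR (60) and 30 for the difference of IR response in Sesn2-KO (8). Limma voom with quality weights called 2637 for IR in young WT, 3436 in aged WT (1054 with edgeR) and 1233 in Sesn2-KO. It called 184 and 18 for age in sham and IR, 2179 and 229 for Sesn2-KO in sham and IR, and 13 for the response difference. With only the compared groups in the fit the counts were 163 for IR in young WT, 0 for aged against young IR and 4 for Sesn2-KO against young WT IR. The length covariate gave 2019 and 2116 for IR in young and aged WT, 40 for age in sham, and 1678 and 192 for Sesn2-KO in sham and IR. Without the length-tilted libraries these were 16 and 106 for IR, 1 and 3 for age in sham and IR, 144 for Sesn2-KO in sham, 55 in IR and 0 for the response difference. For Sesn2-KO against young WT in IR the share of higher genes was 71.7%, and 50% with DESeq2, 56.8% with voom, 53.6% with the length covariate, 55.6%, 48.6% and 55.7% without young IR 2, young IR 3 and Sesn2-KO IR 1, and 41.8% without the length-tilted libraries; 24 of these 55 genes were also called with all libraries.

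Leaving out 1 library at a time gave 272 to 1464 genes for IR in young WT, 236 to 1079 in aged WT and 0 to 1 in Sesn2-KO. It gave 4 to 14 for age in sham and 1 to 17 in IR, 296 to 456 for Sesn2-KO in sham and 9 to 97 in IR, and 2 to 16 for the response difference in Sesn2-KO. The response difference in aged WT stayed at 0 in each of these. The correlation of IR effects was 0.76 to 0.84 between aged and young WT and 0.47 to 0.64 between Sesn2-KO and young WT, and that of age and Sesn2-KO effects 0.45 to 0.65 in sham and 0.55 to 0.74 in IR. With no filter on low counts these correlations were 0.42, 0.16, 0.48 and 0.48, against 0.83, 0.57, 0.60 and 0.65 with it. The 185 calls of genes named in the text, where a gene counts once per comparison, numbered 144 to 180 without single libraries, 121 with only the compared groups in the fit, 61 without the length-tilted libraries and 170 to 184 under the other alternatives. List tests gave 160 calls over the 9 comparisons with camera, 146 to 169 without single libraries, 143 with the length covariate and 137 without the length-tilted libraries, but 2 with an estimated correlation and 37 with fry.

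The replicate numbers of the titles do not pair the samples: correlations of same-numbered libraries' deviations were -0.27 to 0.72, and 6 of 18 libraries were closest to a library of their own number. With the number as a replicate block the counts were 879, 1236 and 0 for IR in young WT, aged WT and Sesn2-KO, 20 and 11 for age, 755 and 68 for Sesn2-KO, and 0 and 6 for the response differences. DESeq2 left 1 named gene's adjusted p undefined. The odds ratio for called genes near Sesn2 in sham was 0.81 (Fisher's exact p = 0.847) within 5 Mb and 0.60 (exact p = 0.0687) within 20 Mb, against 0.75 within 10 Mb. After IR it was 3.39 (exact p = 0.124) within 5 Mb, 1.14 (exact p = 0.695) within 20 Mb and 1.86 within 10 Mb, from 2 called genes.

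Depth limits what can be seen of genes below about 1 CPM, which is 9 to 14 counts per library. For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real counts and the highest of the others were 841 and 0 for IR in young WT (1 split as large, the real one), 1054 and 0 in aged WT (1) and 0 and 0 in Sesn2-KO (10). They were 21 and 0 for age in sham (1), 9 and 17 in IR (2), 708 and 0 for Sesn2-KO in sham (1), and 60 and 209 in IR (2). The splits with 17 and 209 genes put both length-tilted IR libraries on one side; with the length covariate the real counts were 11 and 192. For the IR response of aged against young WT the real count was 0, so that 100 of 100 splits were at least as large whatever the data, and the splits decide nothing. The highest other gave 355, in a split that exchanged the sham and IR labels of all aged libraries and kept most young ones, so that the IR effect itself enters it.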

Other observations

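Here tests of explanations were chosen after the result was seen. List tests were planned.

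Some markers of resident macrophages were also higher in Sesn2-KO sham hearts. Of 14 tested, 4 rose against young WT (8 adjusted over the list alone; 1 without the 6 length-tilted libraries), with a median of 0.60, a camera adjusted p of 9.3e-05 and adjusted p = 0.37 with an estimated correlation. Vsig4, a complement receptor gene of macrophages, was at 13 ± 1.72 CPM in Sesn2-KO and 3.44 ± 1.82 CPM in young WT sham hearts (SD, n = 3 each; log2 fold change 1.92 ± 0.31, adjusted p = 0.00239). F13a1 (0.96) and Mrc1 (0.84), also in the monocyte and macrophage list, rose too. With Vsig4 they stayed called without each library. Lyve1 (0.79, adjusted p = 0.0411) was not called without young sham 1 or 2 or Sesn2-KO sham 1 or 3 (adjusted p 0.117 to 0.172), and 3 markers were then called. F13a1 also rose after IR in young WT (0.75 ± 0.15, adjusted p = 0.00842) and aged WT (0.83 ± 0.15, adjusted p = 0.00437). Each call held without any single library.

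A few cell death genes were also higher. Of 27 genes of apoptosis, pyroptosis and necroptosis, 4 rose in Sesn2-KO sham hearts against young WT (4 adjusted over the list alone; camera adjusted p = 0.013, and adjusted p = 0.55 with an estimated correlation). Camera's adjusted p was 0.12 without young sham 1 and 0.11 with the length trend as a covariate, and 1 gene was called without the 6 length-tilted libraries. The inflammatory caspase gene Casp4 was at 13.8 ± 1.43 against 6.06 ± 0.869 CPM (SD, n = 3 each; log2 fold change 1.19 ± 0.20, adjusted p = 0.00274), and Tnfrsf1a, the TNF receptor 1 gene, rose by 0.57 ± 0.11 (adjusted p = 0.00586); neither lost its call without a single library. Of the other 2, Ninj1 (0.62) was not called without young sham 3 (adjusted p = 0.0509), and Bcl2a1b (1.59) not without young sham 1 or 3 or Sesn2-KO sham 1 or 2 (adjusted p 0.0904 to 0.147). The antibody joining chain gene Jchain was at 1.55 ± 0.294 CPM in Sesn2-KO and 0.268 ± 0.203 CPM in young WT sham hearts (log2 fold change 2.44 ± 0.52, adjusted p = 0.0133), and was not called without young sham 3 (adjusted p = 0.0641). It was the 1 called of 11 B and plasma cell markers, whose median was -0.32 (1 adjusted over the list alone; camera adjusted p = 0.28, and 0.021 without Sesn2-KO sham 1).

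Of the 743 genes that rose after IR in aged WT, 235 were called higher in Sesn2-KO sham hearts. Independent lists would share 24.66, perhaps too few, as both tests share dispersions but no library. The number was 113 and 135 without young sham 1 and 3, 118 and 156 without aged sham 1 and 3, 132 without aged IR 1, and 154 without Sesn2-KO sham 2 or 3. Over the 235 genes Sesn2-KO IR lay above young sham hearts by a median of 1.81 (quartiles 1.08 and 3.26, 100% above 0). This argues against exchanged sham and IR labels within Sesn2-KO. Background reads would give a median of 0.00743% of the rise (at most 0.142%), which is no test for genes chosen by their rise. The strain background stays open: 2 of 4 substrain genes tested differed in sham and in IR. Genotype, line and source of the mice cannot be told apart. Loss of Sesn2, surgery and housing were not tested, which needs littermate controls or unoperated hearts.

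Of 40 interferon genes 9 were lower after IR in young WT and 9 in Sesn2-KO sham hearts, and both comparisons use the young sham libraries. Aged against young sham hearts, which use them too, had a median of -0.33 over the list and 0.49 without young sham 3, where camera called it in the other direction (adjusted p = 8.5e-10). Without young sham 3 the numbers were 1 and 2, so that 2 was the highest, with medians of -0.13 and -0.27 in place of -1.02 and -1.21. A single library with a high interferon response, young sham 3, is a candidate explanation of most of the pattern; the value lies between those set for it (at most 1 gene) and against it (at least 5 in each), and camera's adjusted p stayed at 0.0043 in Sesn2-KO sham hearts. The numbers also fell to 4, 1 and 1 without young IR 1, 2 and 3 and to 2 without Sesn2-KO sham 1, 2 or 3, and rose without young sham 1 or 2.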
